A study of Mus musculus with 9 samples.

How the data were processed

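Gene expression was measured on 9 Affymetrix mouse arrays, each hybridised with RNA of 1 sorted cell population from lungs of 4get mice given IL-25. In 4get mice, a green fluorescent reporter marks cells that express the Il4 gene. Per the labels' protocols, each mouse received 0.5 µg of IL-25 in 50 µL into the trachea daily for 4 days, lungs were digested, and CD11b-positive cells were enriched on magnetic columns. Cells of 4 donor mice were pooled for each replicate, 400000 cells were sorted, and 50 ng of total RNA was amplified. By label, 3 arrays held T2M cells, and the eosinophil, neutrophil and macrophage labels had 2 arrays each. By the labels, each replicate is thus a pool, and the spread between replicates is a spread between pools.

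The deposited values are log2 expression values per probe set, 1 column per array. Per the submitters' processing notes, RMA, affy and limma were used, with no versions and no settings given in the sources used here. The authors' exact normalization between arrays is therefore not stated. Array medians of the deposited log2 values ran from 5.48 to 5.68, and sorted values differed between arrays. A difference of 1 on the log2 scale was read as a 2-fold difference, as for RMA values.

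The table held 45101 probe sets, of which 64 control probe sets were left out of the tests. Platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Among the probe sets with 1 symbol, 34741 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID, which changed 0 symbols. No gene was named from a probe set with several symbols. For each of 18193 genes, the probe set with the highest mean over all 9 arrays was kept, and 9010 genes had more than 1 probe set to choose from. Coordinates were not used here.

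Differences between labels were tested with limma 3.58.1 in R 4.3.3 (lmFit on group means, contrasts, eBayes, two-sided) on all 9 arrays, which shared 1 estimate of the spread. The fit had 5 residual degrees of freedom and a prior of 3.26 degrees of freedom with a prior SD of 0.328. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. The 6 contrasts cover every pair of labels, and the 3 with T2M were the main ones. Each difference is given on the log2 scale as first label minus second, with the standard error (SE) of limma. The number of arrays limits the precision, with a median SE of 0.308 for the T2M contrasts and 0.337 for the others.

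A total of 27 gene lists was fixed before the data were examined. They covered the sorting markers, type 2 cytokines, alternative activation, markers of the myeloid, lymphoid, structural and erythroid cell types the sort could hold, inflammatory and interferon genes, and general programmes. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a contrast. The second form rests on the 5 residual degrees of freedom of the fit, so it is stricter even where the estimated correlation is low. Counts of called members are given over all genes and adjusted over the list alone.

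Named genes followed a rule fixed at the same time. For each T2M contrast these were the 8 largest called differences in each direction without overlap of arrays, and 5 in each direction for other contrasts. From each list described, up to 4 called and up to 2 uncalled members with the largest differences were taken. All sorting and type 2 genes were included. For genes higher or lower in 1 label than in each other, the first 15 (T2M) or 5 (other labels) by smallest difference were taken. Predicted genes without a name were skipped, and the text prints part of the genes so taken, mainly for the lists it describes.

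The test was tried on simulated data with 200 genes changed in the T2M arrays among 18193. For T2M against eosinophils, 84.0% of genes changed by 2 on the log2 scale and 4.0% of those changed by 1 were called, with 7 calls among unchanged genes. These values were drawn independently, with the same mean and spread for all labels before the change. The real contrasts differ in this, so the rates need not hold for them. For sets of genes higher or lower in 1 label than in each other, 100 simulations set that label to the level of the nearest other label, with the spread of the fit. These were added after the data were examined. Alternatives covered the choice of probe sets, a filter on dim genes, scaling between arrays, moderation of the spread, array weights, the samples in the fit, the replicate number as a block, a 2-fold minimum and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.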

Results

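Expression was compared between 4 CD11b-positive cell populations sorted in parallel from inflamed lungs of IL-25-treated 4get mice, to set T2M (type 2 myeloid) cells against eosinophils, neutrophils and macrophages. The T2M gate took cells positive for the Il4 reporter, negative for the IL-5 receptor alpha chain, positive for the macrophage antigen F4/80, low in MHC class II and intermediate in Gr-1. The eosinophil gate took reporter-negative, IL-5 receptor-positive cells with high Gr-1, the neutrophil gate reporter-negative, receptor-negative, Gr-1-positive cells, and the macrophage gate F4/80-positive, MHC class II-positive, Gr-1-negative cells. There were 3 T2M arrays and 2 of each other label, and all p-values take each array as a separate pool of 4 donor mice, as the labels state. For the macrophage-labelled arrays, which correlated at 0.995 against 0.922 to 0.974 for other replicate pairs, the values leave open whether they hold 2 pools or 1 RNA hybridised on both arrays.

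Of the genes behind the gates, 8 of 11 were examined. Ly6g, Ly6c1 and Ly6c2, which encode the Gr-1 antigens that every gate used, were not analysed here. Il4, which the reporter marks and the sort selected on, was at a log2 level of 8.62 ± 1.08 (SD, n = 3) on the T2M-labelled arrays, against 5.24 ± 0.19, 5.55 ± 1.25 and 4.83 ± 0.09 (n = 2 each) on arrays labelled eosinophils, neutrophils and macrophages. It was called higher in T2M than in eosinophils (log2 difference 3.38, SE 0.66, adjusted p = 0.0276) and macrophages (3.79, adjusted p = 0.00828), and not against neutrophils (3.07, adjusted p = 0.0512). The call against eosinophils ended in 6 of 9 fits that left out 1 array and under 2 of 9 other ways of processing, with differences from 2.79 to 3.84. Il5ra, the IL-5 receptor alpha chain, went against the gates. Its level was 7.58 ± 0.44 (n = 3) on T2M-labelled arrays, sorted as receptor-negative, and 5.19 ± 0.83 (n = 2) on the receptor-positive eosinophil-labelled arrays. That difference of 2.40 (SE 0.61) did not pass the test (adjusted p = 0.0678), nor did 2.45 against neutrophils (adjusted p = 0.0793), whereas 3.80 against macrophages did (adjusted p = 0.00591). Populations are therefore named by the label of their arrays throughout. Adgre1, which encodes F4/80, was 1.27 higher in T2M than in eosinophils without passing the test (adjusted p = 0.102). H2-Eb1, an MHC class II chain, was lower in T2M than in macrophages (-2.10, adjusted p = 0.0324), while H2-Aa (-1.21), H2-Ab1 (-1.49), Cd74 (-1.48) and Itgam (0.85) did not pass there. Of 8 sorting genes measured, 1 was called higher against eosinophils (3 adjusted over the list alone, camera adjusted p = 0.00969, and adjusted p = 0.237 with an estimated correlation). Against neutrophils 0 were called, or 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.966). Against macrophages 2 were higher and 1 lower, or 2 and 4 adjusted over the list alone, with a mean difference of 0.34, a median of -0.34 and a downward camera test (adjusted p = 0.857).

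**Figure D1:**
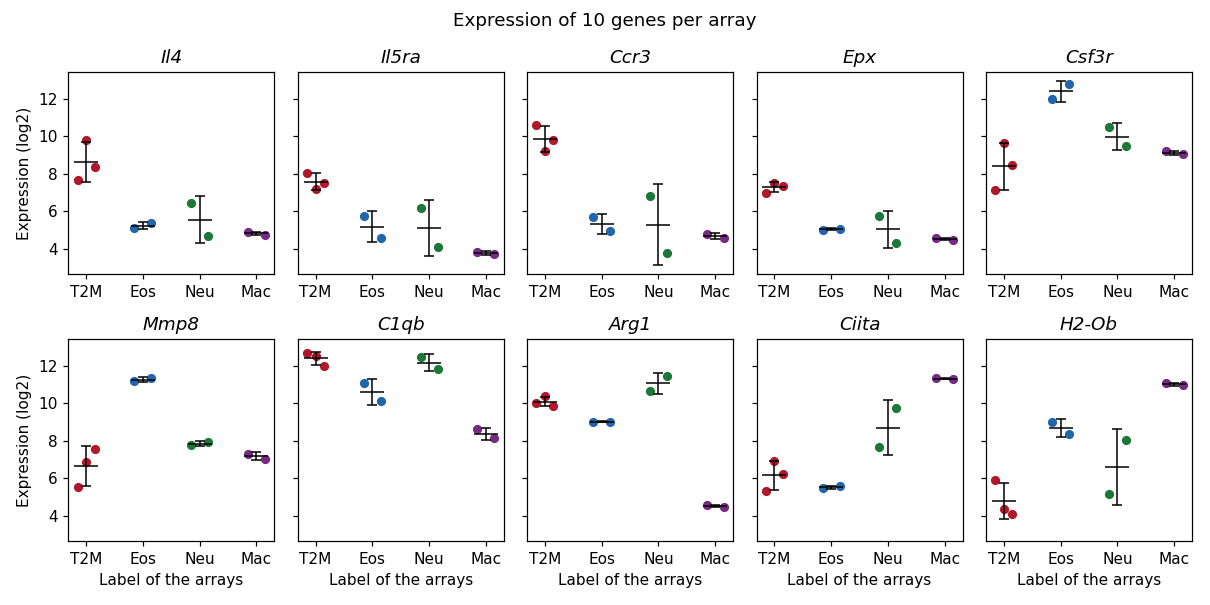
Expression of 10 genes on each array (log2, vertical axis) by array label (horizontal axis); points are single arrays, and black marks give the mean and SD of 3 T2M-labelled arrays or 2 arrays of each other label. Il4, Ccr3 and Epx are highest on T2M-labelled arrays, Csf3r and Mmp8 on eosinophil-labelled arrays, and Ciita and H2-Ob on macrophage-labelled arrays.

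T2M-labelled against eosinophil-labelled arrays: 7 of 14 eosinophil genes were higher in T2M and 9 of 21 neutrophil genes were lower. Ccr3, the eotaxin receptor, was 23.2-fold higher in T2M (log2 difference 4.53, SE 0.79, adjusted p = 0.0187), and Gata1, a transcription factor of the eosinophil and erythroid lineages, differed by 3.75 (SE 0.45, adjusted p = 0.00539). Alox15, a lipoxygenase, differed by 2.97, the nucleotide receptor gene P2ry14 by 2.96, and Epx, eosinophil peroxidase, by 2.24. Of 14 eosinophil genes measured, 7 were called higher and 0 lower, 7 were not called, and 9 were higher when adjusted over the list alone. Prg2, major basic protein, did not pass at a difference of 3.89 (SE 1.31, adjusted p = 0.159), nor did Il5ra. The list was shifted upward by camera (adjusted p = 1.14e-06), which was lost with an estimated correlation (adjusted p = 0.159).

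In the same comparison, the neutrophil list had 9 of 21 members called lower in T2M, 0 higher and 12 not called, or 15 lower when adjusted over the list alone. These included Cd177 (-4.93), the collagenase Mmp8 (-4.59), the G-CSF receptor Csf3r (-3.98) and Wfdc21 (-3.93), while Stfa3 (-3.86) and Asprv1 (-3.10) did not pass. Csf3r stood at 12.39 ± 0.55 (SD, n = 2) on eosinophil-labelled arrays, 9.98 ± 0.72 (n = 2) on neutrophil-labelled arrays and 8.41 ± 1.26 (n = 3) on T2M-labelled arrays. Secondary granule genes had 6 of 14 members lower and 8 not called, or 7 lower and 1 higher adjusted over the list alone, with Ceacam10 66.0-fold lower (-6.04, SE 0.47, adjusted p = 0.00105), and Lcn2 (-4.61), Camp (-3.85) and Olfm4 (-3.43) also lower and Ngp (-2.49) and Cybb (1.11) not called. Camera gave adjusted p = 1.70e-15 for the neutrophil list and 1.15e-05 for secondary granule genes. With an estimated correlation these were adjusted p = 0.158 and adjusted p = 0.159.

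Of interferon-response genes, 12 of 24 were called lower in T2M, 0 higher and 12 not called, or 17 lower adjusted over the list alone. Irf7 (-3.74), Oas3 (-3.56), Rsad2 (-3.22) and Gbp2 (-3.12) differed most, and Irf9 (-2.04) and Oas2 (-1.82) did not pass (camera adjusted p = 7.81e-16, and adjusted p = 0.0578 with an estimated correlation). Among proinflammatory genes 5 of 21 were lower, 2 higher and 14 not called, with the same counts adjusted over the list alone. Il23a (-4.81), Tnf (-3.02) and Nlrp3 (-2.62) were lower and Il6 higher (3.06) in T2M, and Il18 (-1.51) and Nos2 (-1.38) did not pass (camera adjusted p = 3.61e-05, and adjusted p = 0.158 with an estimated correlation). Of 27 chemokine genes, Ccl2 (1.38), Ccl9 (1.30) and Ccl6 (0.94) were higher and Cxcl10 (-1.92) was lower, with 23 not called, among them Ccl4 (-1.91), and 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.536). The chemokine receptor and adhesion list had 2 higher, Ccr3 and C3ar1 (2.25), and 3 lower, among them Cxcr2 (-2.82) and Ccr1 (-2.09), of 23 members, with Ccr7 (2.83-fold higher) and Selplg (-1.24) not called. Adjusted over the list alone 2 were higher and 4 lower, and its mean of 0.02, median of -0.02 and downward camera test (adjusted p = 0.597) differed in sign.

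Type 2 genes were mixed between T2M and eosinophils. Of 18 measured, only Il4 was called higher, and Il1rap (-3.52) and Il13ra1 (-2.71), receptor chains for IL-1 family cytokines and IL-13, were lower, with 15 not called and 2 higher and 3 lower adjusted over the list alone. The list's mean was -0.09 and its median 0.05, with a downward camera test (adjusted p = 0.597). Il13 (1.08, adjusted p = 0.0562) and Il5 (1.26, adjusted p = 0.376) did not pass. The IL-25 receptor chain Il17rb gave 0.33 and its partner Il17ra -0.88, with adjusted p = 0.696 and 0.255. The remaining members, Crlf2 (-0.65), Csf2 (0.80), Gata3 (0.83), Il10 (-0.42), Il13ra2 (0.41), Il3 (0.33), Il4ra (-0.81), Il9 (0.14), Stat5a (-0.38), Stat6 (-0.78) and Traf3ip2 (-0.05), did not pass either.

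Macrophage genes C1qc (1.84) and C1qb (1.79), of the complement C1q complex, were higher in T2M than in eosinophils and Cd14 (-2.19), an endotoxin co-receptor, was lower. The other 21 of 24, among them Axl (1.97) and Mertk (1.41), were not called, and 5 were higher and 2 lower adjusted over the list alone. The alternative activation list had Clec10a (2.00) and Slc7a2 (1.82) higher, Clec7a (-1.28) lower and 21 of 24 not called, among them the scavenger and mannose receptor genes Cd163 (2.25) and Mrc1 (2.11), with 9 higher and 2 lower adjusted over the list alone. By camera, these 2 lists had adjusted p = 0.00402 and 0.00148, with adjusted p = 0.237 and adjusted p = 0.322 with an estimated correlation. Ribosomal protein genes had 5 of 18 higher and 13 not called, or 8 higher adjusted over the list alone. Rpl4 (1.83), Rps18 (1.30), Rpl6 (1.28) and Rpl22 (1.18) were higher and Rps9 (-1.77) was not called (camera adjusted p = 8.82e-05, and adjusted p = 0.159 with an estimated correlation). Epithelial, endothelial and stromal genes had 1 of 25 called higher, the surfactant gene Sftpd (1.82), or 4 adjusted over the list alone, and Cdh5 (2.42) was among 24 not called. The camera test of that list gave adjusted p = 8.11e-04, and adjusted p = 0.272 with an estimated correlation. Beside these lists, 201 ubiquitous genes had a median difference of 0.32, with 6 higher and 4 lower, and the Gapdh control difference was 2.91 in T2M and 1.75 in eosinophils.

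Glucocorticoid-response genes had 3 of 17 lower in T2M than in eosinophils, Il1r2 (-3.28), Hsd11b1 (-2.44) and Fkbp5 (-1.31), and Per1 (-2.11) and Mt1 (1.44) were among 14 not called. Adjusted over the list alone, 9 were lower and 3 higher (camera adjusted p = 0.00421, and adjusted p = 0.189 with an estimated correlation). Lipid mediator genes had Alox15 higher and the prostaglandin receptor Ptger2 (-3.47) lower among 20, with Pla2g4a (1.56) and Ptgir (-1.31) among 18 not called. Their mean was 0.01, their median -0.06 and the camera test downward (adjusted p = 0.958), with 2 higher and 1 lower adjusted over the list alone. Myeloid transcription factors had Gata1 and Zeb2 (1.86) higher, Id1 (-2.78) lower and 23 of 26 not called, among them Nfe2 (-1.84) and Gfi1 (-1.51), or 3 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.348). Oxidative killing genes had Epx higher and 11 of 12 not called, among them Cat (2.70) and Rac2 (-1.58), with 3 higher and 1 lower adjusted over the list alone. Their mean was 0.05, their median -0.19 and the camera test downward (adjusted p = 0.922).

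Single members were called in 4 more lists between T2M and eosinophils. In antigen presentation H2-Ob (-3.89), an MHC class II modifier, was lower and 23 of 24 were not called, among them Ccr7 (2.83-fold higher), with 1 lower adjusted over the list alone (camera adjusted p = 0.0281, upward, and adjusted p = 0.49 with an estimated correlation). Among T cell and innate lymphoid genes Cd3d (-1.80) was lower and Cd3e (1.62) and Il2ra (1.41) were among 22 not called, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00469, upward, and adjusted p = 0.272 with an estimated correlation). Of 13 B cell genes Bank1 (3.43) was higher, also adjusted over the list alone, and Ms4a1 (1.90) and Ighm (1.53) were not called (camera adjusted p = 0.0442, and adjusted p = 0.209 with an estimated correlation). Of 29 cell cycle genes Ccna2 (1.40) was higher, or 3 adjusted over the list alone, and Mcm6 (2.23) and Rrm2 (1.72) were not called (camera adjusted p = 0.00274, and adjusted p = 0.377 with an estimated correlation).

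No member was called in 6 lists between T2M and eosinophils. The 16 alveolar macrophage genes, with Lpl (1.88) and Fabp4 (1.77), had 0 adjusted over the list alone and camera adjusted p = 0.0112, and adjusted p = 0.49 with an estimated correlation. The 21 immediate early genes, with Ier2 (-2.07) and Junb (-1.67), had 5 lower adjusted over the list alone and camera adjusted p = 0.00148, and adjusted p = 0.158 with an estimated correlation. The 18 mast cell and basophil genes, with Cpa3 (2.09), had 1 higher adjusted over the list alone (camera adjusted p = 0.348), and the 13 NK cell genes, with Gzmb (1.46) and Il2rb (1.11), had 0 (camera adjusted p = 0.873). The 10 primary granule genes, with Kit (1.59) and Gfi1 (-1.51), had 1 higher and 1 lower adjusted over the list alone, a mean of 0.07, a median of -0.13 and a downward camera test (adjusted p = 0.873). The 9 erythroid and platelet genes, with Hba-a2 (-2.09) and Ppbp (-1.66), had 0, a mean of -0.12, a median of 0.25 and an upward camera test (adjusted p = 0.873).

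In all, 286 genes were higher and 526 lower in T2M than in eosinophils (limma). By size, Ccr3, Rnf144b (4.39), Selenom (3.98), the kinase gene Fer (3.84), Naaladl1 (3.82), Gata1, Rcn1 (3.73) and Cyp26a1 (3.58) led upward. Ceacam10, Il1f9 (-6.00), Prps1l1 (-5.41), Cd177, Klra17 (-4.85), Il23a, Mgam (-4.75) and Slfn1 (-4.68) led downward. Of these 16 genes, 10 stayed past the threshold under every other processing and 6 also without any 1 array. Across the other fits, the values of Rnf144b ran from 1.65 to 5.15, of Rcn1 from 1.74 to 4.89 and of Slfn1 from -5.27 to -2.52. Shifting arrays to a common median moved the difference of all genes by -0.15 and the share of lower calls from 64.8% to 75.8%. The actin control probe sets differed between 3′ and 5′ ends by 0.61 on T2M replicate 1 and 0.54 on eosinophil replicate 1, and by -0.10 to 0.03 on all other arrays. With the replicate number as a block, which in effect also drops T2M replicate 3, the contrast gave 360 genes in place of 812. The total of 812 fell to 192 without eosinophil replicate 2, 529 without eosinophil replicate 1, 395 and 397 without T2M replicates 2 and 3, and 383 without either macrophage array.

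T2M-labelled against neutrophil-labelled arrays: 6 of 14 eosinophil genes were higher in T2M, and 5 of 24 macrophage genes were lower. Ccr3 (4.57, SE 0.79, adjusted p = 0.0269), Gata1 (4.12), P2ry14 (3.43) and Epx (2.25) were among 6 of 14 eosinophil genes called higher, with 0 lower and 8 not called, or 10 higher adjusted over the list alone. Prg2 (3.91, adjusted p = 0.176) and the sialic acid lectin gene Siglecf (3.23, adjusted p = 0.0534) did not pass. The list's camera test gave adjusted p = 3.99e-11, and adjusted p = 0.226 with an estimated correlation. Il13 was the 1 type 2 gene of 18 called higher (1.33, adjusted p = 0.0386), while Il4ra gave -1.25 (adjusted p = 0.163). The Il13 call ended in each of 9 fits that left out 1 array and under 3 of 9 other ways of processing. Adjusted over the list alone 2 type 2 genes were higher (camera adjusted p = 0.029, and adjusted p = 0.256 with an estimated correlation). Of 21 neutrophil genes, 1 was called, Padi4, a histone-modifying enzyme gene, which was higher in T2M (4.79), and Pglyrp1 (2.42) and Stfa2l1 (2.41) were not, with 4 higher adjusted over the list alone (camera adjusted p = 0.0208, and adjusted p = 0.577 with an estimated correlation).

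Macrophage and monocyte genes had 5 of 24 members lower in T2M than in neutrophil-labelled arrays, with Apoe (-2.67), Cx3cr1 (-2.43), Ccr2 (-2.11) and Cd68 (-1.89), and 19 not called, among them C1qa (-2.08) and Lgmn (-1.69), or 7 lower adjusted over the list alone. The alternative activation list had Ccl24 (-3.32), an eotaxin, and Irf4 (-1.41) lower, and 22 of 24 not called, among them Mgl2 (-2.75), or 8 lower adjusted over the list alone. Both lists had camera adjusted p = 9.03e-05, with adjusted p = 0.256 and adjusted p = 0.388 with an estimated correlation. Antigen presentation genes had Irf8 (-2.11) called lower and 23 of 24 not called, or 4 lower adjusted over the list alone (camera adjusted p = 0.00273, and adjusted p = 0.395 with an estimated correlation). Of ribosomal protein genes, 2 of 18 were called lower, Rps19 (-3.18) and Rpl11 (-1.47), and 16 were not called, among them Rps9 (-3.20), or 10 lower adjusted over the list alone. Their camera test gave adjusted p = 4.74e-07, or adjusted p = 0.226 with an estimated correlation. On structural lung genes, Sparc (2.65), Krt18 (2.10) and Sftpd (2.02) were higher in T2M and 22 of 25 not called, among them Col3a1 (2.22) and Sftpb (2.14), or 4 higher adjusted over the list alone (camera adjusted p = 7.11e-07, and adjusted p = 0.256 with an estimated correlation). Of 29 cell cycle genes Ube2c (-1.61) and Top2a (-1.36) were lower and Mcm2 (-2.05) and Tpx2 (-1.63) were not called, or 8 lower adjusted over the list alone (camera adjusted p = 9.03e-05, and adjusted p = 0.388 with an estimated correlation). RNA measures moved with these macrophage, ribosomal and cell cycle lists, as 201 ubiquitous genes had a median difference of -0.80, with 19 lower and 0 higher, and the Gapdh control difference was 2.91 in T2M and 1.83 in neutrophils.

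The 2 neutrophil-labelled arrays stood apart from each other, with a correlation of 0.922 and 4111 genes over 2-fold apart. The mean of 13 NK cell genes, relative to the mean of the labels, was 1.11 on replicate 1 and -0.68 on replicate 2, and that of the neutrophil list was 0.21 and -1.17. The 228 genes higher and 285 lower in T2M rest on that spread. They were led upward by F2r (5.67), the thrombin receptor, Cd55 (5.54), Padi4, Ccr3, Naaladl1 (4.54), Dach1 (4.28), Cd69 (4.25) and Ctla2a (4.25). Downward, Ssr4 (-3.71), Uck2 (-3.36), Ccl24, Sdc1 (-3.26), Pid1 (-3.23), Rps19, the proteasome gene Psmb7 (-3.09) and Tmem14c (-2.95) led. Of these 16 genes, 0 stayed past the threshold under every other processing, which the fit of these labels alone, with 0 calls, settled in advance. Ssr4 was at 0.62, the other direction, without probe sets shared between transcripts, and its call ended under 5 of 9 other ways of processing. Fitted on the 5 arrays of these labels alone, limma called 0 genes, with 2256 at an unadjusted p under 0.05. Quantile normalization moved the share of lower calls from 55.6% to 39.5%. Array weights gave 24.5% of 53 calls. The replicate block, which in effect also drops T2M replicate 3, gave 30.2% of 43. Other processing with calls gave 46.7% to 60.4%. The total of 513 rose to 897 without neutrophil replicate 1 and was 108 without either macrophage array, 237 without T2M replicate 2 and 112 without T2M replicate 3.

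T2M-labelled against macrophage-labelled arrays: this comparison had the most calls of the T2M contrasts, with 1188 genes higher and 1935 lower in T2M. Of eosinophil genes, 12 of 14 were called higher, 13 adjusted over the list alone, among them Alox15 (7.72, SE 0.50, adjusted p = 1.77e-04), Siglecf (6.13), Ccr3 (5.17) and Prg2 (5.11). The remaining call was lower in both counts, the cadherin gene Cdh17 (-1.25), and Csf2rb (0.85) was not called. Of neutrophil genes, 13 of 21 were called higher, 0 lower and 8 not called, or 14 higher adjusted over the list alone, including Padi4 (5.62), Clec4e (5.09), Trem1 (4.95) and G0s2 (4.23), with Fpr2 (1.96) and S100a9 (1.94) not called. Camera gave adjusted p = 1.48e-07 and 5.61e-07 for these lists, and adjusted p = 0.188 and adjusted p = 0.275 with an estimated correlation.

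Between T2M-labelled and macrophage-labelled arrays, chemokine genes had 14 of 27 higher in T2M, 1 lower and 12 not called, or 16 higher and 2 lower adjusted over the list alone, led by Cxcl3 (7.34), Ccl8 (6.92), Ccl12 (5.82) and Ccl7 (5.80), with Ccl22 (1.83) and Cxcl14 (1.74) not called. Proinflammatory genes had 10 of 21 higher, 1 lower and 10 not called, or 12 higher and 2 lower adjusted over the list alone, led by Il1a (6.66), Il6 (6.50), Vegfa (4.85) and the cyclooxygenase gene Ptgs2 (4.56), with Il18 (-1.86) and Lif (1.73) not called. The camera tests of these 2 lists gave adjusted p = 1.48e-07 and 2.27e-05, and adjusted p = 0.16 for both with an estimated correlation. Type 2 genes had 5 of 18 higher and 1 lower, Stat5a (-1.25), or 8 and 1 adjusted over the list alone, including Il13 (1.76), Il10 (1.65) and Il13ra2 (1.42), while Csf2 (2.01, adjusted p = 0.0684) and Il5 (1.75, adjusted p = 0.0898) did not pass (camera adjusted p = 0.0591). Alternative activation genes moved both ways, with 9 higher, 5 lower and 10 not called of 24, or 9 and 7 adjusted over the list alone. Slc7a2 (6.97), an arginine transporter, Arg1 (5.56), arginase, and Ccl17 (3.39) were higher and the lectin gene Cd209a (-4.52) was lower (camera adjusted p = 0.173).

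Of antigen presentation genes, 11 of 24 were called lower in T2M, 1 higher and 12 not called, or 17 lower and 2 higher adjusted over the list alone. H2-Ob (-6.23), the MHC class II transactivator Ciita (-5.16), Cd209a and H2-DMa (-4.25) differed most, and Ccr7 (-1.62) and Itgae (1.49) were not called (camera adjusted p = 2.94e-06, and adjusted p = 0.207 with an estimated correlation). Macrophage and monocyte genes went both ways, with 8 higher, among them Pf4 (5.47), C1qb (4.01) and C1qc (3.25), and 3 lower, among them Cx3cr1 (-2.96), and 13 not called, among them Gpnmb (2.19), or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0509). Interferon-response genes had 6 of 24 lower and 18 not called, or 8 lower and 1 higher adjusted over the list alone, with Usp18 (-3.20), Oas3 (-3.14), Mx1 (-2.48) and Stat2 (-1.66) lower and Irf9 (-1.43) not called. Ribosomal protein genes had 8 of 18 lower and 10 not called, or 14 lower adjusted over the list alone, with Rps19 (-3.88), Rps14 (-3.40), Rpl11 (-1.81) and Rpl19 (-1.75) lower and Rps9 (-3.73) and Rpl8 (-2.69) not called. The camera tests gave adjusted p = 0.00116 and 4.89e-07 for interferon and ribosomal genes, and adjusted p = 0.207 and adjusted p = 0.16 with an estimated correlation.

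Structural lung genes had 13 of 25 members higher in T2M than in macrophage-labelled arrays and 12 not called, or 17 higher adjusted over the list alone, with Tek (4.32), Cdh1 (3.60), Sparc (3.50) and Sftpa1 (3.03) higher and Col3a1 (2.74) and Sftpc (2.52) not called (camera adjusted p = 2.94e-06, and adjusted p = 0.207 with an estimated correlation). Their mean, relative to the labels' mean, was 1.41, 0.90 and 0.71 on the T2M-labelled arrays and -1.08 and -0.87 on the macrophage-labelled arrays. RNA measures moved with the labels as well. The Gapdh control probe sets differed by 2.91 ± 0.54 (SD, n = 3) between 3′ and 5′ ends on T2M-labelled arrays and by 1.11 ± 0.12 (n = 2) on macrophage-labelled arrays, and 201 ubiquitous genes had a median difference of -1.10.

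The largest differences upward were Alox15, F2r (7.56), Cxcl3, Slc7a2, Ccl8, Acod1 (6.87), Il1a and Il6, and downward H2-Ob, Dnase1l3 (-5.49), Bcl11a (-5.18), Ciita, Abcg3 (-5.04), Stra6l (-4.92), Bex6 (-4.89) and Pid1 (-4.60). All 16 stayed past the threshold under every other processing and without any 1 array. The total of 3123 was 434 and 514 without macrophage replicates 1 and 2, 1938 and 1764 without T2M replicates 2 and 3, and 5070 without either neutrophil array. The macrophage-labelled arrays correlated at 0.995 with 32 genes over 2-fold apart, against 996 to 4111 genes for the other replicate pairs. They were counted as 2 replicates, and every contrast uses their spread, which would be too small if 1 RNA was hybridised on both.

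Genes apart from all 3 other labels were counted next. In T2M, 55 genes were higher than in each other label, against at most 13 (mean 4.77) in 100 simulations that set T2M to the level of the nearest other label and kept the differences among the other labels. Simulations without any effect, which the adjustment holds near 0, gave 0, and independent lists 0.234. Ccr3, Naaladl1, Gata1, Cyp26a1, Vgf, Aspa, Ikzf2, F2r, Cd55, P2ry14, Slc24a3, Tpbg, Peg10, Bank1 and Rmdn2 led, with smallest differences from 4.53 to 2.58. A further 40 genes were lower in T2M than in each other label, against at most 14 (mean 6.34) in the same kind of simulation and 0.876 for independent lists. These were led by Ifitm6 (at least 2.67 lower), Havcr2, Prex1, Niban1, Borcs6, Zfp106, Matk, Mefv, Ifitm2, Gch1, Plac8, Krcc1, the interferon gamma receptor gene Ifngr1, Plbd1 and Otulinl. Part of each excess over independent lists may come from the arrays the contrasts share. The simulations keep these arrays but draw each gene and array independently, with 1 spread per gene for all labels. Replicate pairs differed in spread, at 32 to 4111 genes over 2-fold apart, and some arrays deviated together. The simulated counts may thus be too low, and the excess over them is no measure of chance. In fits of each pair of labels alone, limma called 0 of both sets, with 246 and 220 genes at an unadjusted p under 0.05. The 0 calls of T2M against neutrophils in these fits settled that in advance. Array weights left 19 and 5, and the replicate number as a block left 7 and 4. The block in effect also drops T2M replicate 3, and leaving out that array alone gave 16 and 9. Without 1 array the counts ran from 9 (without eosinophil replicate 2) to 82 (without neutrophil replicate 1) and from 7 (without either macrophage array) to 62 (without neutrophil replicate 1).

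Eosinophil-labelled arrays had 284 genes higher than in each other label, led by Ceacam10, Prps1l1, Il1f9, Klra17 and Il23a, against at most 16 in simulations with the nearest label's level and 1.098 for independent lists. Macrophage-labelled arrays had 159, led by the nuclease gene Dnase1l3, Stra6l, Adam23, Abcg3 and Dtx1, against at most 21 and 2.519. Neutrophil-labelled arrays had 16, led by the syndecan gene Sdc1, Htr7, Stac2, Ramp3 and Vcan, against at most 12 (mean 5.66) and 0.140. Simulations without any effect gave at most 1 gene in these sets. The simulations at the nearest label's level have the same limits here as for T2M. Leaving out 1 array gave 115 to 315, 19 to 710 and 1 to 130 genes.

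**Figure D2:**
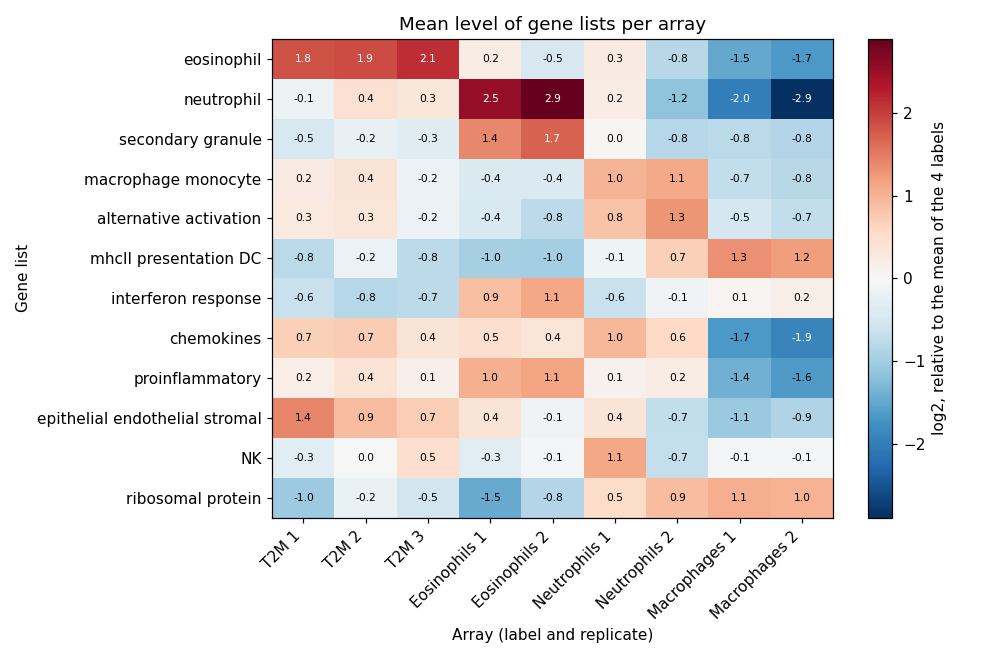
Mean log2 level of 12 gene lists (rows) on each of 9 arrays (columns), relative to the mean of the 4 labels, as colour and number. Eosinophil genes are highest on the 3 T2M-labelled arrays (1.83 to 2.14), neutrophil genes on the 2 eosinophil-labelled arrays (2.54 and 2.89), antigen presentation genes on the macrophage-labelled arrays (1.31 and 1.22), and macrophage and monocyte genes on the neutrophil-labelled arrays (0.99 and 1.09).

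Among the other pairs, eosinophil-labelled against neutrophil-labelled arrays gave 645 higher and 788 lower genes. Of neutrophil genes, 12 of 21 were called higher on the eosinophil-labelled arrays, 0 lower and 9 not called, or 18 higher adjusted over the list alone (camera adjusted p = 5.39e-17, and adjusted p = 0.11 with an estimated correlation). Ceacam10 (6.79), Olfm4 (6.51), Prps1l1 (5.63), Wfdc21 (5.54) and Klra17 (5.36) led. Macrophage genes had 9 of 24 lower and 15 not called, or 14 lower adjusted over the list alone (camera adjusted p = 2.03e-07, and adjusted p = 0.11 with an estimated correlation), and Sdc1 (-4.52), Vav2 (-4.33), Pa2g4 (-4.25), Hacd1 (-4.17) and Pid1 (-4.05) led downward. Ubiquitous genes had a median difference of -1.14 in this contrast, with 53 of 201 lower and 2 higher, and 11 of 18 ribosomal protein genes were lower, 0 higher and 7 not called, or 15 lower adjusted over the list alone (camera adjusted p = 2.46e-11, and adjusted p = 0.11 with an estimated correlation). Of 14 eosinophil genes, 1 was higher and 1 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.38). Shifting arrays to a common median moved all differences by 0.15 and the share of lower calls from 55.0% to 43.4%. The total of 1433 fell to 710 without eosinophil replicate 2.

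Against macrophage-labelled arrays, the eosinophil-labelled arrays had 1071 genes higher and 2092 lower. Ubiquitous genes had a median difference of -1.49, with 98 of 201 lower and 1 higher, and the Gapdh control difference was 1.75 in eosinophils and 1.11 in macrophages. The total of 3163 fell to 862 and 990 without macrophage replicates 1 and 2, and to 1982 and 1824 without eosinophil replicates 1 and 2. Cxcl3 (8.64), Acod1 (7.92), Olfm4 (7.64), the histidine decarboxylase gene Hdc (7.31) and Ceacam10 (7.25) were higher. Cd209a (-6.22), Ciita (-5.80), Pid1 (-5.41), Cyp4f16 (-5.37) and the immunoglobulin gene Igha (-5.29) were lower. The neutrophil-labelled arrays had 206 genes higher and 206 lower than the macrophage-labelled arrays. Macrophage and monocyte genes went against these labels, with 6 of 24 higher on the neutrophil-labelled arrays, 0 lower and 18 not called, or 11 higher adjusted over the list alone (camera adjusted p = 2.26e-07, and adjusted p = 0.124 with an estimated correlation). Relative to the labels' mean, that list stood at 0.99 and 1.09 on the neutrophil-labelled arrays and at -0.71 and -0.81 on the macrophage-labelled arrays. Slc7a2 (6.92), Ccl8 (6.91), Cxcl3 (6.73), Alox15 (6.60) and Arg1 (6.54) were higher, and Dnase1l3 (-5.80), Stra6l (-5.51), Hbb-b2 (-4.75), H2-Oa (-4.65) and H2-Ob (-4.41) were lower. These 412 calls rose to 3009 without neutrophil replicate 2 and fell to 87 and 75 without macrophage replicates 1 and 2.

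**Figure D3:**
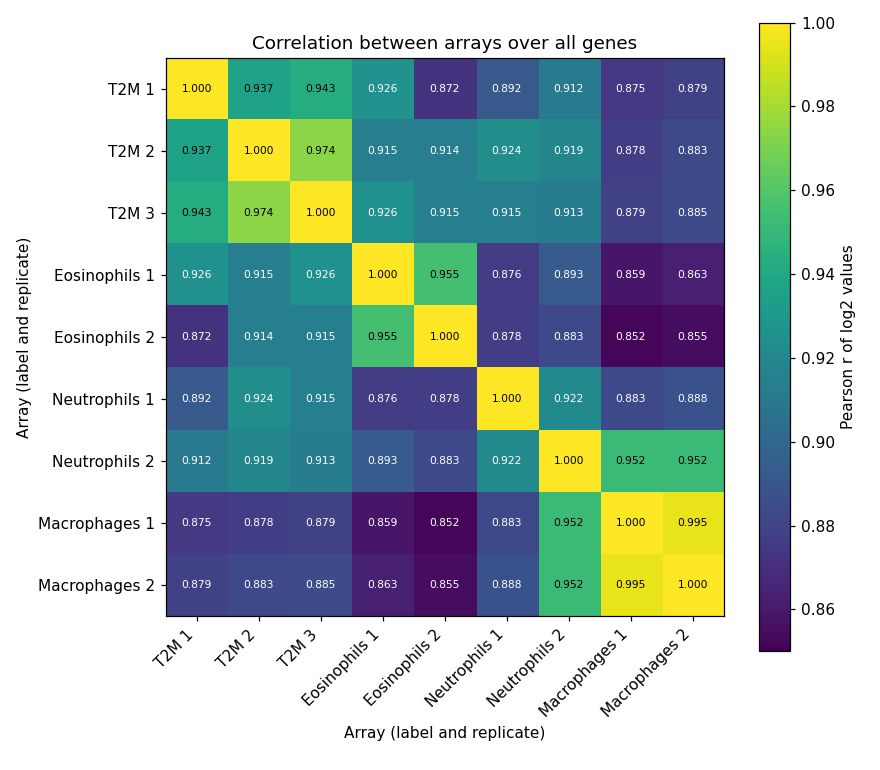
Pearson correlation of log2 values over all genes between each pair of the 9 arrays (rows and columns, by label and replicate). Neutrophil-labelled replicate 2 correlates at 0.952 with a macrophage-labelled array and at 0.922 with its own replicate.

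Across all genes, which are not independent replicates, correlations between arrays of 1 label ran from 0.922 (neutrophils) to 0.995 (macrophages), with 0.937 to 0.974 for T2M and 0.955 for eosinophils. T2M replicate 1 was the farther of its label, at 0.937 and 0.943 to the others. Between labels, mean correlations were highest for neutrophils and macrophages (0.919), followed by T2M and neutrophils (0.912), T2M and eosinophils (0.911), and lowest for eosinophils and macrophages (0.857). The first rank rests on neutrophil replicate 2, at 0.952 to both macrophage-labelled arrays, as replicate 1 was at 0.883 and 0.888.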

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

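The setting without T2M replicate 1 and neutrophil replicate 1 together was chosen after the data were seen. T2M replicate 1 stood apart from its label, and neutrophil replicate 1 from replicate 2. This setting leaves neutrophil replicate 2, at 0.952 to the macrophage-labelled arrays, as the only neutrophil array, so it is not a cleaned set. All other alternatives were planned. The filter on dim genes and leaving out shared probe sets did not hold every named gene, and a gene counted as staying where it was not held. Of 305 called gene differences taken by the naming rule, 157 stayed past the threshold under every processing alternative in this sense. Among the 305, 64 were of T2M against neutrophils, and 0 of these could stay, since the fit of these labels alone called 0 genes. No gene list kept an adjusted p under 0.05 with an estimated correlation. For the type 2 list in T2M against neutrophils, the camera adjusted p went from 0.029 to 0.256. Its estimated correlation, -0.043, lay below the preset 0.01. The loss thus does not measure correlation among members alone. A 2-fold minimum, shifting arrays to a common median, leaving out probe sets shared between transcripts and a filter on dim genes kept all 11 counts within 1.5 times. Leaving out such shared probe sets turned Mt1 in T2M against macrophages to -1.05 and Ssr4 in T2M against neutrophils to 0.62 through a different probe set.

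Averaging probe sets gave 252 genes higher in macrophages than in each other label. Quantile normalization gave 26 genes lower in T2M than in each other label, and eBayes with trend and robust gave 21, with 10 higher in neutrophils. Fits of 2 labels alone, which have fewer arrays, gave 397, 0 and 4988 genes for T2M against eosinophils, neutrophils and macrophages. They gave 215 and 5219 for eosinophils against neutrophils and macrophages, and 151 for neutrophils against macrophages. Higher than in each other label were then 0 genes in T2M, 77 in eosinophils, 0 in neutrophils (117 at an unadjusted p under 0.05 in limma) and 43 in macrophages, and 0 were lower in T2M. The 0 calls of T2M against neutrophils settled these counts of 0 in advance. Array weights gave, in the same order, 1426, 53 and 10163 for T2M and 526 and 6400 for eosinophils. They left 19 genes higher in T2M, 0 in neutrophils (113 at an unadjusted p under 0.05) and 5 lower in T2M. The cause of these shifts was not tested.

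Same-numbered arrays deviated together for T2M with eosinophils (0.50 for replicate 1 and 0.44 for replicate 2) and not for the other 10 of 12 pairs (lowest -0.18). In labels of 2 arrays the deviations mirror each other, so these pairs are not separate evidence. As 4 of 9 arrays correlated best with their own number, the numbers were not taken to pair all labels. For T2M with eosinophils a pairing stays open, and it may affect the unblocked counts of that contrast. The replicate number as a block took T2M against eosinophils from 812 to 360 genes and gave 43 and 1733 for the other T2M contrasts and 263 for neutrophils against macrophages. It gave 7, 171, 3 and 92 genes higher in T2M, eosinophils, neutrophils and macrophages than in each other label, and 40 became 4 for those lower in T2M. Only T2M has a replicate 3, so the block fits that array exactly and in effect drops it. Leaving out T2M replicate 3 with no block gave 397, 112 and 1764 genes for the T2M contrasts. Part of the fall may thus come from the lost array. Chance counts for the blocked fit were not simulated.

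Without the 2 arrays that stood apart, the T2M contrasts gave 1789, 2019 and 6372 genes, eosinophils against neutrophils 2842 and against macrophages 5748. Genes higher than in each other label numbered 182 in T2M, 399 in eosinophils and 85 in neutrophils, and 215 were lower in T2M. The NK list, not called in T2M against neutrophils, then passed with the opposite direction (adjusted p = 0.0052).

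Leaving out 1 array, where a lone array is assumed to vary like the other labels, gave 192 to 1211, 108 to 897 and 434 to 5070 genes for T2M against eosinophils, neutrophils and macrophages. It gave 710 to 1821 and 862 to 4320 for eosinophils against neutrophils and macrophages, and 75 to 3009 for neutrophils against macrophages. Genes higher than in each other label ran from 9 to 82 in T2M, 115 to 315 in eosinophils, 1 to 130 in neutrophils and 19 to 710 in macrophages, and 7 to 62 were lower in T2M. The NK list in T2M against neutrophils ran from an adjusted p of 0.0296 to 0.967, with 0.0441 and the opposite direction without neutrophil replicate 1. Signal over background was not analysed here, which leaves dim genes without a detection limit.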

Other observations

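Further lists held genes called between T2M-labelled and macrophage-labelled arrays. The alveolar macrophage list had 6 of 16 members higher and 0 lower, or 8 and 2 adjusted over the list alone, with Car4 (6.39), Plet1 (4.58) and Fabp5 (3.33) higher (camera adjusted p = 0.0045, and adjusted p = 0.442 with an estimated correlation). Mast cell and basophil genes had 4 of 18 higher and 1 lower, or 5 and 1 adjusted over the list alone, with Hdc (5.23) and Osm (3.99) higher and Kit (-1.85) lower (camera adjusted p = 0.0073, and adjusted p = 0.28 with an estimated correlation). Lipid mediator genes had 5 of 20 higher and 0 lower, or 6 and 0 adjusted over the list alone, including Alox5 (4.72) and Pla2g4a (1.27) (camera adjusted p = 0.129). Chemokine receptor and adhesion genes had 6 higher and 3 lower of 23, or 6 and 6 adjusted over the list alone, with Ccr1 (5.09) and the C5a receptor gene C5ar1 (3.38) higher and Cx3cr1 (-2.96) lower (camera adjusted p = 0.691). Myeloid transcription factors had 7 higher and 6 lower of 26, or 8 and 8 adjusted over the list alone, with Gata1 (4.32) and Ets2 (3.85) higher and Irf8 (-2.70) and Cebpa (-2.42) lower (camera adjusted p = 0.709). Immediate early genes had 4 higher and 4 lower of 21, or 6 and 4 adjusted over the list alone, with Socs3 (2.98, or 0.59 and not called without probe sets shared between transcripts) higher and Ier2 (-2.07) and Jun (-1.75) lower (camera adjusted p = 0.709).

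All tests below were chosen after the results they bear on had been seen, and each is a hypothesis tested on the data that raised it.

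Eosinophil genes were higher on T2M-labelled arrays than on arrays labelled eosinophils. A mixture of the other 3 labelled populations lies between its parts, yet 5 eosinophil genes (Epx, Prg3, Ccr3, Gata1 and P2ry14) were called higher in T2M than in each of them. This argues only weakly against such a mixture, as the 5 genes became 4 without T2M replicate 1 and 1 without T2M replicate 2 or 3. Against eosinophils and neutrophils, the calls ended in 8 and 7 of 9 fits leaving out 1 array for P2ry14 and 6 and 8 for Prg3. They ended in 4 and 4 for Epx, 3 and 4 for Ccr3 and 0 and 0 for Gata1 (lowest difference of all 1.54). Fits of 2 labels alone called 0 of the 5 genes against neutrophils, which was settled in advance, as they called 0 of all genes there. An exchange of the eosinophil and neutrophil labels cannot be told apart, since the values point both ways. The eosinophil list was also 2.22 higher in T2M than on neutrophil-labelled arrays (camera adjusted p = 3.99e-11, and adjusted p = 0.226 with an estimated correlation), which goes against it. Eosinophil genes were not higher on neutrophil-labelled than on eosinophil-labelled arrays, as an exchange would have them. Eosinophil-labelled minus neutrophil-labelled arrays gave a mean of 0.14, with 1 of 14 higher and 1 lower (camera adjusted p = 0.38). However, 12 of 21 neutrophil genes were higher and 0 lower on eosinophil-labelled than on neutrophil-labelled arrays (mean 3.20), which goes with it. An exchange of the T2M and eosinophil labels cannot be told apart either, since Il4 was 3.38 higher in T2M, as the gate selects, in a call that ended in 6 of 9 fits leaving out 1 array, while Il5ra was 2.40 higher there, against the gate and without passing the test. Eosinophils outside the eosinophil gate, and a T2M population that itself carries these transcripts, stay open and were not tested.

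Neutrophil-labelled replicate 2 was closer to the macrophage-labelled arrays than to its own replicate. Across 201 ubiquitous genes the median was 0.72 higher on replicate 2, with 88.6% of them higher. Loss of their signal in replicate 1 would give such a rise and may account for part of the closeness. Macrophage-labelled cells in replicate 2 would give it too. The mean level of these genes was 9.50 and 9.39 on the macrophage-labelled arrays, 9.51 on replicate 2 and 8.75 on replicate 1. This test therefore cannot separate loss in replicate 1 from gain in replicate 2. Macrophage-labelled cells in replicate 2 remain open. Among 52 genes abundant on the macrophage-labelled arrays, 6 (11.5%, exact 95% interval 4.4% to 23.4%) lay below 7.54% of the macrophage level on replicate 2, where the median gene stood at 30.2%, against 13.7% on replicate 1, and that interval spans the bound of 10%. The 52 genes had a mean log2 level over 9 in macrophages, more than 2.5 above every T2M-labelled and eosinophil-labelled array. Dnase1l3, the lowest of them at 1.57%, stood at 5.65 on replicate 2, 6.05 on replicate 1 and 11.64 in macrophages. At the other end, Fkbp4 stood at 93.93% of the macrophage level on replicate 2 and 39.41% on replicate 1.

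More genes were lower than higher in T2M-labelled than in macrophage-labelled arrays, at 62.0% of calls. Array weights turned this balance, with 47.4% of 10163 calls lower, while other ways of processing gave 54.8% to 68.3%. The balance also turned, narrowly, without macrophage replicate 1, a fit that leaves a lone macrophage array. Ubiquitous genes had a median difference of -1.10 and the Gapdh 3′ to 5′ difference was 2.91 in T2M and 1.11 in macrophages. Both follow these labels, so RNA loss cannot be told apart from the cell type between them. On other arrays the Gapdh difference and the mean level of ubiquitous genes came apart. Eosinophil replicate 2 had 1.09 and 8.00, against 1.02 and 9.50 on macrophage replicate 1. Within T2M, the array with the largest Gapdh difference (3.43) had the highest level (8.47). The neutrophil-labelled arrays went with RNA loss, at 2.20 with 8.75 and 1.45 with 9.51. A larger Gapdh difference thus did not always go with lower ubiquitous genes. Within the eosinophil label, the 1935 genes lower in T2M had a median of -0.15 on the array with the larger Gapdh difference, with 59.7% of them lower, and of -0.02, with 51.5% lower, on the T2M array with the largest Gapdh difference against the others, where all genes gave 0.00 and -0.01, so these few arrays leave a 3′ bias open. The 40 genes lower in T2M than in each other label gave -0.27 (67.5% lower) and 0.09 in these 2 comparisons, and the 55 higher genes gave 0.11 and -0.11.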
